A study of Homo sapiens with 4 samples.

How the data were processed

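The series holds 4 Agilent whole human genome arrays of 1 colour (Cy3), from A549 cells grown in medium with 20% serum and electroporated with siRNA. Per the labels, each labelling began from 500 ng of RNA. Per the file headers, the scanner images were read with Agilent Feature Extraction 9.5.3.1, and the deposited values are linear spot intensities, background-subtracted and detrended within each array but not scaled between arrays. Its above-background and outlier flags, per the file headers, are 0 or 1. The authors' deposited table gives an unsigned fold for each siRNA array against the control array. Compared with the scanner files, these folds equal ratios of processed signal after division by each array's 75th percentile, within 0.01 log2 for all but 1 probe. The tool behind the table is not given in the sources used here. All 4 arrays lay on 1 slide and in 1 scan, so no batch could be tested. The 75th percentile of the processed signal was 744, 733 and 634 on the siRNA arrays and 767 on the control array, and no spot was saturated.

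Control spots and spots with an outlier flag were left out, and spots of 1 probe were averaged (264 probes were spotted 10 times). Each log2 intensity had the log2 of its array's 75th percentile subtracted. A probe was tested when well above background on the control array or on all 3 siRNA arrays, which left 28684 of 41000. Probes were named through RefSeq accessions without versions (a RefSeq table on assembly GRCh38.p14, used for names only). A symbol was found for 23434 probes, 57.2%, and the other 17566 are unnamed here. No coordinates are given, because the header names another build. A gene was represented by its probe of highest mean signal, which gave 12694 genes.

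The 3 siRNA arrays, 1 per siRNA, were compared with the control array with lmFit and eBayes in limma 3.58.1 (R 4.3.3), with 2 residual and 3.1 prior degrees of freedom. Benjamini-Hochberg adjustment ran over all tested probes, with a threshold of 0.05. Values are mean log2 ratios ± SD of the 3 ratios. A gene not well above background in a group, or on an siRNA array where siRNAs are compared, has only a bound there, written "at least N-fold", against the higher of its own signal and the lowest signal among probes well above background. Before the data were examined, 28 gene lists with 533 genes, the tests, the alternatives and the rule for named genes were fixed. Lists with at least 5 tested members (26) were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. List medians were also placed among 10000 random lists matched on signal. The rule named NFE2L2, KEAP1, up to 12 called genes per direction by the smallest of the 3 ratios, up to 4 members of each list described by size of the mean ratio, and up to 4 genes per siRNA by the gap to the nearer siRNA.

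The scripts were tested on simulated arrays made with the real means and a spread drawn from limma's prior, the same for all 4 arrays. In each of 5 runs 200 genes were changed among 28684 probes. For NRF2 siRNA against control, limma called 0.299% of genes changed by 1 log2, 34.3% of those changed by 2 and 80.3% of those changed by 3, with 4.4 false calls per run. The simulated arrays held no spots lit on 1 array alone, whereas each real array held 60 to 69. Such spots made up 15 of the called lower genes in the real data. The false calls per run therefore do not cover them. A shift of 1 log2 in the NRF2 target list was called by camera's preset correlation in 20 of 20 runs and with an estimated correlation in 0 of 20. In those runs 0.882% of the lists that had not been shifted were called. The simulated genes were drawn independently of each other, whereas the estimated correlation within the real lists reached 0.77. This rate therefore does not cover lists of correlated genes.

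Alternatives were normexp background correction (on the median signal, since the files hold no mean signal), quantile normalization, median scaling, no filter on dim probes, a filter on all 4 arrays, the mean over the probes of a gene, each siRNA array left out in turn, eBayes with trend and robust options, and other thresholds. Settings added after the data were seen left out probes near spots lit on the control array alone, or dim genes. No alternative had been planned for the differences between siRNAs.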

Results

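RNA was measured in A549 cells, a human lung adenocarcinoma line that carries a mutant KEAP1 and so holds its transcription factor NRF2 (gene NFE2L2) active. The cells had been electroporated with 1 of 3 different siRNAs against NRF2, or with a control siRNA, and were harvested after 24 hours. Each of the 3 NRF2 siRNAs has 1 array (siRNA 1, 2 and 3 below), and the control siRNA has 1 array. All 4 samples lay on 1 slide. Between 27743 and 29461 of the 41000 probes were well above background on the siRNA arrays, and 28471 on the control array. The number of arrays limits the precision, and the labels do not say that the samples were separate cultures. The limma p-values measure only the spread between the 3 siRNA arrays, which holds differences between siRNAs. The single control array was assumed to vary like those arrays. Camera's p-values compare the genes of a list with all other genes. With the preset correlation they do not measure how far a result repeats over siRNAs or control arrays.

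The targeted gene was read first. NFE2L2 signal was lower with each siRNA, at log2 ratios to the control of -2.37 with siRNA 1, -1.90 with siRNA 2 and -2.38 with siRNA 3. The mean was -2.22 ± 0.28 (SD, n = 3), which is 4.65-fold lower. The limma adjusted p was 0.076 over all probes, which did not pass the threshold, while the mean ratio was larger than the spread between the 3 siRNAs. KEAP1, whose product marks NRF2 for degradation, had a mean log2 ratio of -0.80 ± 0.06 (SD, n = 3; limma adjusted p = 0.19).

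The question of the series was which transcripts change when NRF2 is silenced. The clearest group was the NRF2 antioxidant and detoxification targets, of which 47 of 52 were measured. In this list 41 genes fell when adjusted over the list alone, none rose and 6 did not pass, while 7 fell over all genes tested. The list median was -1.31 log2, with -1.50, -1.20 and -1.33 for the 3 siRNAs, and 45 members were below the control on every siRNA array. GPX2, a glutathione peroxidase, had the greatest decrease of this list at a mean log2 ratio of -3.98 ± 0.96 (SD, n = 3). CYP4F11, a fatty acid hydroxylase, followed at -3.63 ± 0.40, NQO1, a quinone reductase, at -3.04 ± 0.67, and SLC7A11, the cystine transporter, at -2.90 ± 0.55. The limma adjusted p over the list alone was 0.0043 for GPX2 and 0.00076 for CYP4F11. FTL and ABCC1 were among the 6 that did not pass, and their ratios were -3.04 and -2.67 with siRNA 1, against -1.15 and -0.36 with siRNA 2 and -0.96 and -0.70 with siRNA 3. Camera gave an adjusted p of 6.9e-38 with its preset correlation. This call is lost with an estimated correlation (adjusted p = 0.14), while fry gave an adjusted p of 0.036. The estimated correlation called a simulated shift of 1 log2 in this list in 0 of 20 runs. Failing it therefore does not show that a shift is absent, here or for the lists below.

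**Figure D1:**
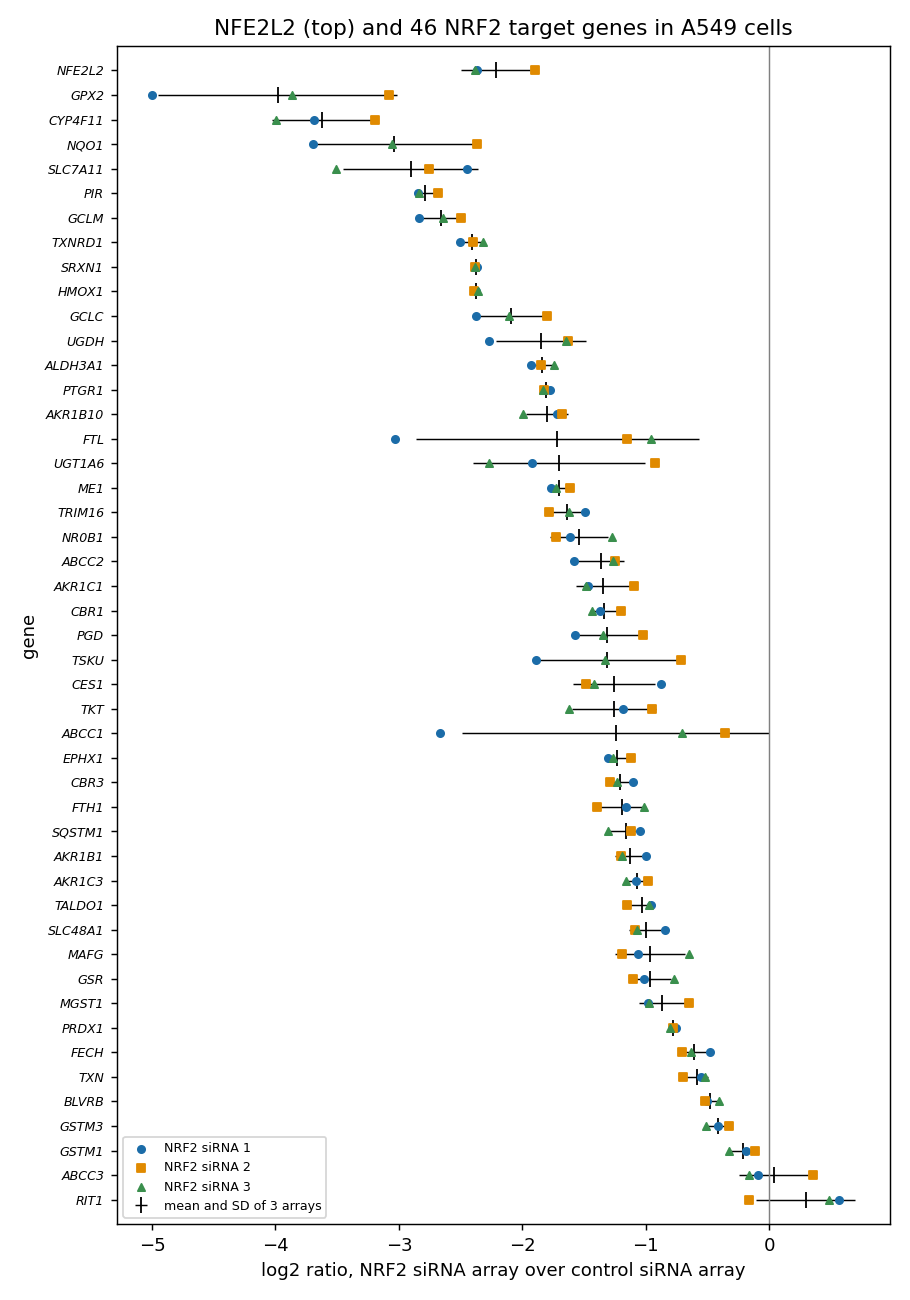
Log2 ratio of each NRF2 siRNA array to the control siRNA array (x axis) for NFE2L2 and 46 of the 47 measured NRF2 targets (y axis); coloured points are the 3 siRNAs, and black marks with bars are their mean and SD (n = 3). Of the 46 targets drawn 44 lie left of 0 with all 3 siRNAs, with NFE2L2 at a mean of -2.22 and the median of the whole list at -1.31.

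Several enzyme groups tied to NRF2 were lower together. Every gene named in this paragraph is also on the NRF2 target list, so these lists are not separate evidence from it. Of the 22 measured aldo-keto and carbonyl reductases and aldehyde dehydrogenases, 11 fell when adjusted over the list alone, none rose, and 1 fell over all genes (median -1.08 log2). Among them were NQO1, ALDH3A1 at -1.84 ± 0.10, PTGR1 at -1.81 ± 0.03 and AKR1B10 at -1.80 ± 0.17 (SD, n = 3). Of 14 genes of the pentose phosphate pathway and NADPH supply, 5 fell over the list alone and none over all genes (median -0.70). ME1, malic enzyme, was at -1.70 ± 0.08 and PGD at -1.31 ± 0.28. TKT, transketolase, was at -1.25 ± 0.34. Of 27 genes of glutathione synthesis and use, 7 fell over the list alone and 1 over all genes (median -0.37). These included GCLM and GCLC, the subunits of the rate-limiting enzyme of glutathione synthesis, at -2.66 ± 0.17 and -2.09 ± 0.29. Camera with its preset correlation gave adjusted p-values of 4.9e-12, 9.4e-06 and 2.6e-07 for these 3 lists. With an estimated correlation the adjusted p was 0.30 for each.

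Amino acid and iron genes were also lower. Of the genes named in this paragraph, HMOX1, FTL and ABCC2 are also on the NRF2 target list. So are SLC7A11 of amino acid supply, FTH1, BLVRB, FECH and SLC48A1 of heme and iron, and ABCC1 and ABCC3 of efflux. These lists are therefore not wholly separate evidence from it. Among 25 measured genes of serine and amino acid supply that ATF4 controls, 11 fell and 1 rose when adjusted over the list alone, and none passed over all genes (median -0.48). CBS, which makes cystathionine, was at -1.72 ± 0.19, ASNS, asparagine synthetase, at -1.39 ± 0.10 and PSAT1, of serine synthesis, at -1.30 ± 0.16. The 1 riser was DDIT3, a stress-induced transcription factor, at 1.29 ± 0.28, chosen after its values were seen. Of 16 heme and iron genes, 5 fell and 1 rose over the list alone, and 1 fell over all genes (median -0.54). HMOX1, heme oxygenase, was at -2.38 ± 0.02 and ABCB6 at -1.37 ± 0.06, FTL did not pass at -1.72 ± 1.15, and HAMP, the iron hormone hepcidin, rose at 1.34 ± 0.28. Of 8 drug efflux transporters (median -0.45) 3 fell over the list alone and none over all genes: ABCB6, ABCC2 at -1.37 ± 0.19 and ABCG2 at -0.94 ± 0.17. Adjusted p-values by camera's preset correlation were 1.5e-08 for amino acid supply, 5.3e-04 for heme and iron and 0.016 for efflux. None of the 3 passed with an estimated correlation (adjusted p = 0.30, 0.32 and 0.32), which had missed the simulated shift as well.

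Genes of DNA replication were lower as a group, with 23 of 24 below the control on all 3 siRNA arrays (median -0.53), but none passed when adjusted over the list alone. MCM6, a helicase subunit, was at -0.99 ± 0.88, with -2.01 for siRNA 1 and -0.48 for each of the others. CDC45 was at -0.83 ± 0.38 and FEN1 at -0.81 ± 0.12 (SD, n = 3). Camera's adjusted p was 8.6e-09 with the preset correlation and 0.36 with an estimated correlation, which was itself 0.65. Smaller median shifts passed the preset test in 5 further lists. They were fatty acid synthesis (median -0.48, adjusted p = 0.0044), purine synthesis and folate carbon (-0.27, 2.1e-04), glycolysis (-0.27, 0.0042), cell cycle and mitosis (-0.26, 3.4e-04) and proteasome subunits (-0.12, 0.0012). With an estimated correlation their adjusted p ran from 0.31 to 0.52. For cell cycle and mitosis that correlation was 0.55, and the medians were -0.47, -0.07 and -0.31 for the 3 siRNAs. Over the list alone ME1, which is also on the NRF2 target list, fell in fatty acid synthesis, as 1 of 12. No member passed in the other 4. Among the values were SREBF1, a regulator of lipid synthesis, at -0.91 ± 0.50, PPAT, the first committed enzyme of purine synthesis, at -1.20 ± 0.52, MTHFD2 at -1.18 ± 0.20 and BUB1B, a mitotic checkpoint kinase, at -0.74 ± 0.26.

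Members of the NF-kB and interferon lists were higher. Of 16 measured genes of NF-kB and inflammatory cytokines, 6 rose over the list alone and none over all genes (median 1.10, or 1.03 with IL24 at its bound). The medians were 1.36, 0.46 and 0.95 for the 3 siRNAs. RELB, an NF-kB subunit, was at 1.44 ± 0.42, and the chemokine CXCL2 at 1.27 ± 0.22. The chemokine CXCL1, at 1.48 ± 0.64, did not pass. IL24 was not well above background on the control array and was at least 1.98-fold higher. Camera gave an adjusted p of 2.5e-05, lost with an estimated correlation (adjusted p = 0.36), which was itself 0.49. Of 18 measured interferon response genes 4 rose over the list alone (median 0.36), among them OASL at 1.68 ± 0.27, ISG15 at 1.11 ± 0.19 and IFIT1 at 1.03 ± 0.19, with a camera adjusted p of 0.0026 (adjusted p = 0.31 with an estimated correlation). RIGI did not pass at 1.04 ± 0.37. The p53 targets had a median of 0.40 with no member past the threshold over the list alone, MDM2 at 1.03 ± 0.24, GADD45A at 0.92 ± 0.31 and CDKN1A at 0.91 ± 0.17 included (camera adjusted p = 0.0032, and adjusted p = 0.32 with an estimated correlation). In the mesenchymal list (median 0.32) SPARC alone rose over the list alone, at least 2.21-fold because it was not well above background on the control array (camera adjusted p = 0.0085, and adjusted p = 0.31 with an estimated correlation). The unfolded protein response had a median of 0.23 and no member past the threshold, ATF6 at 0.79 ± 0.12 included (camera adjusted p = 0.024, and adjusted p = 0.36 with an estimated correlation). Without a filter on dim probes the interferon response and the unfolded protein response did not pass, at adjusted p = 0.13 and 0.080.

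**Figure D2:**
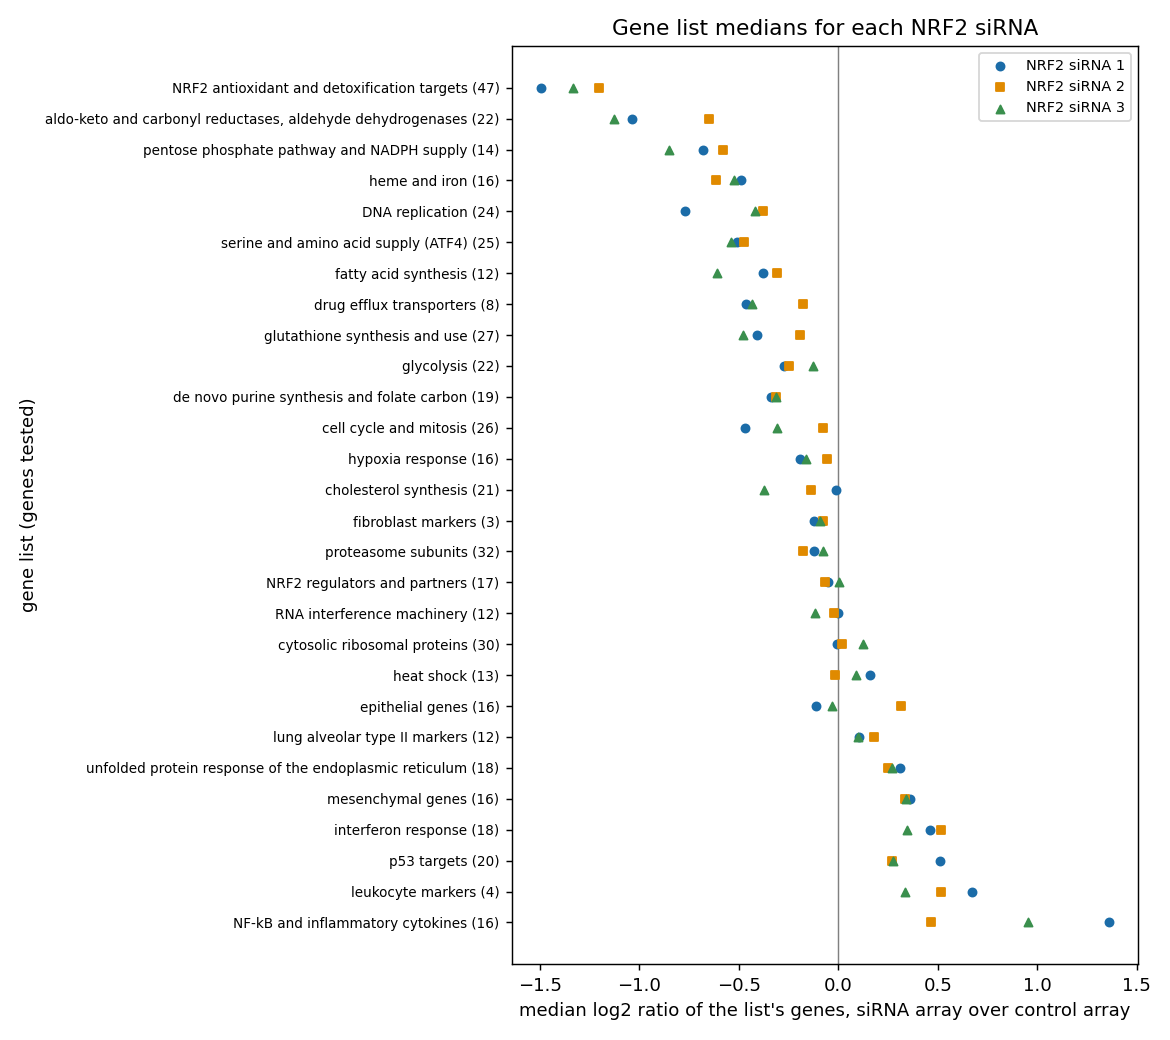
Median log2 ratio of each fixed gene list to the control array (x axis), for each of the 3 NRF2 siRNAs (coloured points), with the number of genes tested in brackets (y axis). NRF2 targets lie lowest with all 3 siRNAs (-1.50, -1.20 and -1.33), and the NF-kB and cytokine list is at 1.36, 0.46 and 0.95, highest with siRNA 1 and siRNA 3 but not with siRNA 2.

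Other lists did not pass with camera. The 30 measured cytosolic ribosomal protein genes had a median of 0.04 (adjusted p = 0.93), the 12 RNA interference genes 0.04 (0.73), the 13 heat shock genes 0.05 (0.38) and the 12 alveolar type II markers 0.15 (0.52). With median scaling the first 3 medians turned to -0.05, -0.05 and -0.03. Medians were -0.18 for the 21 cholesterol genes (adjusted p = 0.068) and -0.26 for the 16 hypoxia genes (0.54), with a hypoxia mean just above 0 against a negative median. Among random lists matched on signal, the cholesterol median lay at percentile 1.4 and the hypoxia median at 0.31. Random lists do not carry the correlation within a list. The cholesterol list passed with normexp, without a filter on dim probes and without siRNA 1 or siRNA 2. For the RNA interference list the test pointed down while the median and mean were above 0. In the epithelial list (median 0.09, or -0.01 without siRNA 2, adjusted p = 0.50) CDH3, P-cadherin, rose over the list alone at 1.43 ± 0.02. Among 17 regulators and partners of NRF2 (median -0.03, adjusted p = 0.23) the NRF2 relative NFE2 rose over the list alone, at least 2.38-fold because it was not well above background on the control array. SQSTM1, an adaptor that binds KEAP1, and KEAP1 fell over the list alone, SQSTM1 at -1.16 ± 0.14. The small MAF proteins MAFF and MAFG did not pass over this list alone, at 1.13 ± 0.46 and -0.97 ± 0.28, while MAFG was among the 41 that fell over the NRF2 target list alone. Few markers of other cell types were measured. They were 3 of 12 for fibroblasts, with no member past the threshold, and 4 of 12 for leukocytes, where CD68 rose over the list alone at 0.87 ± 0.22.

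Over all 12694 genes limma called 25 lower and 7 higher with NRF2 siRNA at an adjusted p under 0.05, all with the same sign on the 3 siRNA arrays. At an unadjusted p under 0.05 there were 522 lower and 1224 higher, or 799 and 923 with median scaling. The 7 NRF2 targets called were PIR, a pirin, at -2.79 ± 0.09, and SRXN1, sulfiredoxin, at -2.38 ± 0.01, with HMOX1, GCLM, CYP4F11, PTGR1 and TXNRD1, thioredoxin reductase, at -2.41 ± 0.09. SPP1, osteopontin, was at -2.44 ± 0.12 and VEGFD at -2.63 ± 0.07. PIR, SRXN1, TXNRD1, SPP1 and VEGFD were chosen after their values were seen. Of the 25 lower genes, 15 were above background on the control array and on no siRNA array. The rule of size named 10 of those 15, HYDIN, GOT1L1, BLTP3A, RHEX, DNAH8, DMD, PPFIA2, GRM6, NKPD1 and TNIP3, from at least 1.90-fold to at least 22.1-fold lower. It also named CCL17, above background on 1 siRNA array and at least 13.1-fold lower. The 15 genes were themselves spots lit on the control array alone, which follows from how such spots were defined. CCL17, TXNRD1 and GBP5 lay beside such spots, and GBP5 was the 1 higher gene there. The 7 higher genes were SLC24A4, ANPEP, a membrane aminopeptidase at 2.39 ± 0.12, GBP5, a guanylate-binding protein, COMMD8 at 2.16 ± 0.10, KIF25, MYCBPAP at 1.99 ± 0.10 and SPRR2D at 2.04 ± 0.12. Of these SLC24A4, GBP5 and KIF25 were not well above background on the control array, and were at least 1.93-fold, 2.96-fold and 2.40-fold higher. The counts rest on every array: without siRNA 1 limma called 9 lower and 0 higher (333 and 859 at an unadjusted p under 0.05), and without siRNA 2 or siRNA 3 it called 0 (729 and 1504, and 365 and 905). When 5.34% of probes, those lit on the control array alone and their neighbours, were left out after the data were seen, limma called 0 (471 lower and 1192 higher at an unadjusted p under 0.05). This removed 18 of the 32 called genes themselves. The ratios of the 14 called genes left in were unchanged, and for PIR the unadjusted p stayed at 1.8e-05 while its adjusted p went from 0.025 to 0.087, through its rank in the adjustment.

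**Figure D3:**
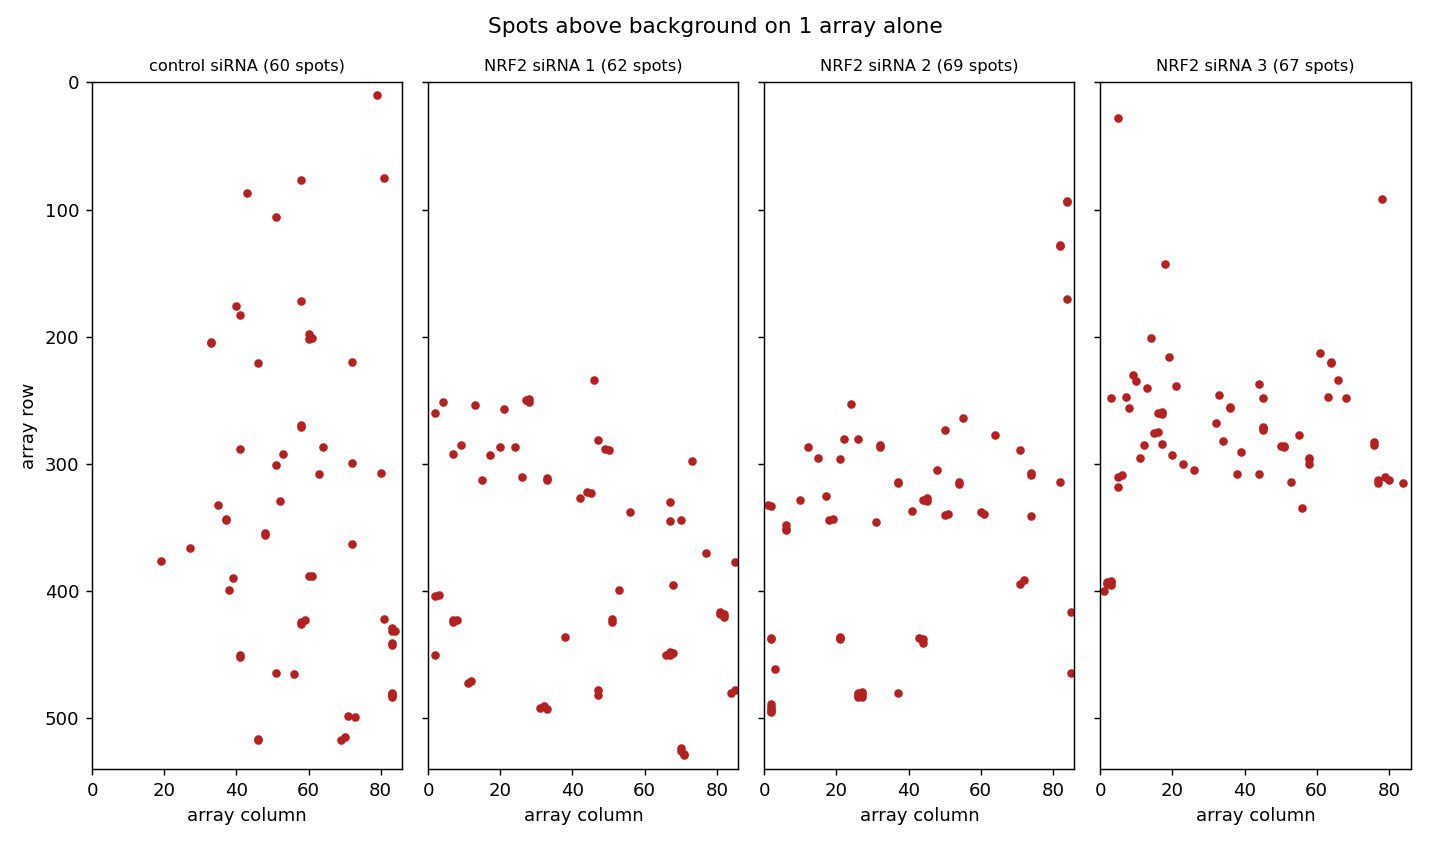
Array row (y axis) against array column (x axis) of the spots at least 4-fold brighter on 1 array than on each other array and above background there alone, 1 panel per array. The control array holds 60 such spots and the siRNA arrays 62, 69 and 67, many side by side.

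By size alone, without a test, 129 genes were at least 2-fold lower and 211 at least 2-fold higher on all 3 siRNA arrays. The counts were 77 and 47 with normexp and 149 and 166 with median scaling. Without probes at or near spots lit on the control array alone, left out after the data were seen, they were 95 and 205. Of the 211 higher genes 56 were not above background on the control array, and of the 129 lower genes 42 were above background on the control array alone, so that their ratios are bounds. Among the 6283 genes above the 75th percentile of signal the split was 42 lower and 34 higher. All 3 ratios share the control array, so its own noise enters each. When each siRNA array in turn was taken as the lone array, 49 to 77 genes were 2-fold lower and 11 to 60 were 2-fold higher, or 0 to 3 and 5 to 25 above the 75th percentile.

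Ratios to the control were alike across the 3 siRNAs. Across the 12694 genes the log2 ratios correlated at r = 0.73 for siRNAs 1 and 2, 0.83 for 1 and 3, and 0.72 for 2 and 3, where genes are not independent replicates. Unchanged arrays sharing 1 control gave 0.50 by simulation. The covariances were 0.22, 0.29 and 0.22 against a simulated 0.052, differences of 0.17, 0.24 and 0.16. The control array could not be split, so its own content enters each pair.

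Differences between siRNAs have no replicate check. At least 2-fold lower or higher than with each other siRNA were 46 and 23 genes for siRNA 1, 87 and 106 for siRNA 2, and 87 and 9 for siRNA 3. With signals not above background held at their bound they were 44 and 19, 81 and 99, and 73 and 7. With normexp they were 32 and 2, 25 and 38, and 36 and 2, and without a filter on dim probes 93 and 110, 235 and 178, and 135 and 131. Against the control array the 46 genes were mostly lower with siRNA 1, 34 of them at least 2-fold, while 51 of the 87 genes lower with siRNA 2 were above the control with siRNA 2. ZMYM6 was at a log2 ratio to the control of -2.67 with siRNA 1 against -0.10 and -0.48 with siRNAs 2 and 3, and MGAT4A at -1.60 against 0.69 and 0.58. TAF15, an RNA-binding protein, was at -0.33 with siRNA 1 and at 2.13 and 2.40 with the others. TMEM121B had a log2 gap of 3.48 between siRNA 1 and the nearer siRNA, and with siRNA 1 was at least 21.8-fold above the control array, where it was not well above background. TKTL1, a transketolase-like gene, was at 0.78 with siRNA 2 and at 3.92 and 4.35 with siRNAs 1 and 3, and VWF, von Willebrand factor, at 0.74 with siRNA 2 and at 3.55 with siRNA 1, the nearer of the others. SCGB1D1 and DEFB106A were well above background with siRNA 2 alone among the siRNAs, and at least 3.62-fold and 3.65-fold higher there than with the nearer siRNA. PCDHGB2 was at 2.81 with siRNA 3 and at -0.42 with siRNA 1, and was not well above background with siRNA 2. GBP1 and SLC5A9 were not well above background with siRNA 3, and were at least 1.52-fold and 2.61-fold lower there than with the nearer siRNA.

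The authors' deposited table lists 1055 probes at least 2-fold changed on all 3 arrays, 709 higher, 337 lower and 9 of mixed direction, and the same 1055 probes met that limit here without a filter on dim probes. NQO1 in the authors' deposited table is 13.0-fold, 5.15-fold and 8.33-fold down with the 3 siRNAs. Of the 709 higher probes 438 were not above background on the control array, and 169 on no array. Of the 337 lower probes 111 were above background on the control array alone. All 68 probes called by limma are in that table.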

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

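Settings that left out probes near spots lit on the control array alone, or genes below the 75th percentile, and all those for differences between siRNAs were chosen after the data were seen. The slide block was not run, because all 4 arrays lay on 1 slide. No paired analysis was possible because the control group has 1 array. Against 25 lower and 7 higher genes in the main setting, the counts were 78 and 49 with normexp, 24 and 2 with quantile normalization (7.69% higher against 21.9%), 0 and 0 without a filter on dim probes (419 and 1290 at an unadjusted p under 0.05 with limma), and 2 and 0 with the filter on all 4 arrays (493 and 1212). They were 11 higher with the mean over probes, 13 higher with the trend and robust options, and 60 and 40 at an adjusted p under 0.10. Without the probes near lit spots they were 0 and 0 (471 and 1192). There 18 of the 32 calls ended because their probes were left out, and the other 14 kept their ratios and ended through the rank in the adjustment. Leaving out 1 siRNA array, which leaves 1 residual degree of freedom, gave 0 to 9 lower (9 without siRNA 1) and 0 higher, with 333 to 729 and 859 to 1504 at an unadjusted p under 0.05. For the other settings the cause was not tested. Of the 32 called genes, 20 were also called with normexp, 24 with quantile normalization and 22 with the trend and robust options. NFE2L2 stayed lower, from -2.38 to -2.13, with adjusted p from 0.013 to 0.32. It passed with normexp (-2.15, adjusted p 0.013) and the trend and robust options (-2.22, adjusted p 0.041). The 2-fold counts, 129 lower and 211 higher, were 77 and 47 with normexp and 83 and 155 with the filter on all 4 arrays. Without a filter 370 were higher, and the counts were 263 and 678 at 1.5-fold and 42 and 34 above the 75th percentile. Leaving out 1 siRNA array gave 248 to 420 higher, the 420 without siRNA 2. Camera with its preset correlation called 18 of 26 lists, and 18 or 19 under each other processing. With an estimated correlation, which found the simulated shift in 0 of 20 runs, it called 0 (NRF2 targets at an adjusted p of 0.14). Fry called 1. The NRF2 target median stayed between -1.45 and -1.26. Over the other tested lists and settings, 203 medians stayed within the SD of the list's 3 siRNA medians, and 47 moved by more. Lists that never passed changed direction. The ribosomal list did so with normexp (adjusted p 0.92), median scaling (0.68), no filter (0.60), without probes near lit spots (0.99) and without an siRNA array (0.55 to 0.82, turned without siRNA 3). The RNA interference list did so with fry (0.88), and the epithelial list without an siRNA array (0.30 to 0.71, turned without siRNA 2). Without a filter the correlations between siRNAs were 0.64, 0.73 and 0.64. Counts for 1 siRNA alone, lower and higher, without a filter were 93 and 110, 235 and 178, and 135 and 131. With normexp they were 2 higher for siRNA 1, 25 and 38 for siRNA 2, and 36 and 2 for siRNA 3, and with the filter on all 4 arrays 2 higher for siRNA 3. Of the 670 tested probes in the authors' table, limma called 68. Over single named genes, 1076 values kept their direction and side of the threshold, 175 lost the call and 38 gained one. Of the gaps of genes named for 1 siRNA, 64 values stayed within 0.188 log2, limma's prior SD, and 13 moved by more. Dim signal limits the ratios, since local background was 45 to 50 on the arrays and 67.7% to 71.9% of probes were well above it.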

Other observations

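All tests in this part were chosen after the result was seen, but for that on other probes of the genes lower with siRNA 1. The genes of the next paragraph were chosen after their values were seen.

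Further members of the lists passed when adjusted over the list alone with limma. In iron handling these were FTH1, ferritin heavy chain, at a mean log2 ratio of -1.19 ± 0.19 (SD, n = 3) and TFRC, the transferrin receptor, at -0.82 ± 0.16. In amino acid supply PHGDH, the first enzyme of serine synthesis, was at -1.18 ± 0.09 and SLC1A4 at -1.23 ± 0.13. In glutathione use GSR, glutathione reductase, was at -0.96 ± 0.17 and CHAC1 at -1.18 ± 0.23. Among inflammatory genes CXCL3, BIRC3 and CXCL5 were at 1.23 ± 0.34, 1.14 ± 0.29 and 1.08 ± 0.32, and IRF7, an interferon regulator, at 0.98 ± 0.12. The heat shock genes HSPA6 and CRYAB did not pass, at 2.49 ± 1.11 and 1.47 ± 0.83.

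Each of the 4 arrays was taken as the lone array in turn, with the filter turned the same way. The real choice gave 32 called genes and the highest of the others 4, so that 1 of 4, the real one, gave as many. Of the 32 genes 15, and all 4 of the others, were spots lit on the lone array alone. With an siRNA array as the lone one, the control array lay in the group of 3. Any difference between control and NRF2 siRNA then widened the spread and lowered the calls. The counts are therefore not like for like, and no conclusion is drawn from them. With 4 choices no share under 0.05 can be reached.

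Genes lit on the control array alone, such as HYDIN, GOT1L1 and RHEX, made up 15 of the 25 called lower genes. The siRNA arrays held 62, 69 and 67 spots of the same kind, so that 60 on the control array was no excess, which argues against loss of the transcripts as the cause for the set. Of the 60 spots 33 had another within 5 rows and 2 columns, against at most 19 in 10000 random draws, which is consistent with local bright spots on the surface of the array. The 1 gene with another tested probe was at -0.08 there, which shows no loss. Loss of other single transcripts stays open, since 15 of these spots were above -3 log2 against 4 to 8 on the siRNA arrays.

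Higher genes outnumbered lower genes among the 2-fold genes, at 62.1% (95% exact binomial interval 56.7 to 67.2, counting error only). Above the 75th percentile of signal the share was 44.7% (33.3 to 56.6), and with normexp it was 37.9% (29.4 to 47.0). With another scaling between arrays it was 52.7% (47.0 to 58.3, median scaling) or 54.7% (49.0 to 60.4, quantile normalization). Among genes above background on all 4 arrays, 155 were 2-fold higher and 83 lower. Signal under background on the control array therefore does not by itself account for the excess. Dim signal above background and the background handling of dim spots may each contribute, and the scaling between arrays stays open. No biological explanation was tested.

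Genes lower with siRNA 1 than with the others numbered 46, among them ZMYM6, and 34 of them were also at least 2-fold below the control with siRNA 1. Of the 16 with another tested probe, 11 had a gap of -0.5 or lower there, 68.8% (exact binomial interval 41.3 to 89.0) against 1.97% of all other probes, with a median gap of -0.66. This argues against single bad spots on that array for these genes, and the others had no other tested probe. With quantile normalization the median gap of the 46 genes was -1.17 against -1.19, and 44 of them stayed at least 2-fold lower. It moved the gaps of the other genes by a median of only 0.034 log2 (95th percentile 0.089). It could not have closed gaps of this size, so the scaling of that array was not tested by it. FTL, ABCC1 and GPX2 are among these 34 and are also on the NRF2 target list, so the set is not wholly separate from NRF2. For those named genes an effect through NRF2 was not separated from an effect of siRNA 1 on other transcripts. For the rest of the 34 an effect of siRNA 1 on transcripts other than NRF2 may be a candidate explanation. It stays open, since the labels give no siRNA sequence.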
